A study of Mus musculus with 8 samples.

How the data were processed

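Total RNA from mouse E14TG2a cells, extracted with Trizol and treated with DNase, was labelled with the Ambion MessageAmp kit and measured on Illumina BeadChips: 8 arrays, 2 in each of 4 groups (ES, IDE2, IDE2+FGF2 and IDE2+FGF10). Per the file headers, the deposited signal intensity is the mean over the beads of a probe on a linear scale, summarised in BeadStudio (version not stated); the values were neither background-subtracted nor normalized. Per the file headers, the deposited bead count is the number of beads behind each probe on each array, and the deposited detection p-value is the share of background probes with at least that signal, as BeadStudio gives it. A second deposited table of intensities held the same rank order on each array (rank correlation 1) with array medians of 144.53 to 144.89; from its values it had been quantile normalized without background subtraction, and per the labels the method was not stated. It served only as an alternative.

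Of 25697 probes, 23978 carried a gene name and 1719 had none here; they named 16593 genes, and 0 symbols needed updating. Median signals were 117 to 175 per array and 45.2 to 52.2% of probes were detected. Signals were corrected and normalized with neqc of limma 3.58.1 in R 4.3.3 (normexp correction with background estimated from the detection p-values, offset 16, quantile normalization, log2). Probes with a detection p under 0.05 on at least 2 arrays were kept (14502, of which 13637 named), and each gene was represented by its probe with the highest mean, leaving 9915 genes. Of 2643 genes with several probes, 49, 9 and 68 had probes called in opposite directions in IDE2, IDE2+FGF2 and IDE2+FGF10 against ES, 1 (Dab1) in IDE2+FGF10 against IDE2, and none in the others. Asns, Dusp6 and Mcm6 were the list genes among them, in IDE2+FGF10 against ES.

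All 8 arrays were fitted in a single limma model with a mean per group (4 residual degrees of freedom, prior degrees of freedom 6.64, prior SD 0.324), and 6 comparisons were made: each differentiated group against ES, IDE2+FGF2 and IDE2+FGF10 against IDE2, and IDE2+FGF10 against IDE2+FGF2. All p-values of single genes are moderated t tests of limma, adjusted by the Benjamini-Hochberg method; a gene changed when its adjusted p was under 0.05. Errors of log2 changes are standard errors from this model, and errors of levels are SDs of 2 arrays. A gene whose probe was not detected on any array of a group was compared with the background level of that group and its fold given as a lower bound; no fold was given where neither group was detected.

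Gene lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists with at least 3 tested members. The 22 lists were pluripotency, epiblast and primitive streak, Nodal and activin targets, definitive endoderm and early gut, extraembryonic endoderm, lung epithelium, other endoderm organs, neural, glia and neural crest, mesenchyme and fibroblast, cardiac and skeletal muscle, endothelium and blood, macrophage and leukocyte, trophoblast, FGF signalling feedback and targets, cell cycle, glycolysis and hypoxia, cholesterol synthesis, p53 response, heat shock and stress, mitochondrial respiration, and cytosolic ribosome. They were written from general knowledge and held 370 entries, of which 329 had a probe and 242 were tested. Some genes, such as Etv5, Gsc and Cdx2, are in 2 lists and count in each. Of 25 lung epithelium genes 12 were below background and 1 had no probe. Camera compares a list with the other genes, and was repeated with a correlation estimated from the data. The estimates lay below the preset value for FGF targets (-0.036), mesenchyme and fibroblast (-0.061) and heat shock and stress (-0.073). Correlation between genes therefore does not explain the higher p of these lists in the repeat. The repeat refers its statistic to the 4 residual degrees of freedom of the fit, which by itself raises p. The test with the preset value uses nearly as many degrees of freedom as there are genes. Estimates for pluripotency (0.035) and mitochondrial respiration (0.27) lay above the preset value, so there the correlation and the degrees of freedom both raise p. Fry tests the direction of a list on balance.

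Groups, comparisons, thresholds, lists and most alternatives were chosen before the data were examined. So was the rule for naming genes: the 8 largest rises and 8 largest falls per comparison among changed genes whose replicates did not overlap, leaving out provisional names; for each list up to 4 members, the 2 largest rises and 2 largest falls that passed, or the member with the smallest p; and always Pou5f1, Nanog, T, Sox17, Foxa2, Cxcr4, Nkx2-1, Sftpc, Sftpb, Scgb1a1, Foxj1, Aqp5, Pax6 and Tubb3. Alternatives were no background correction, median scaling, the second deposited table, no detection filter, a strict filter (detection p under 0.01 on 4 arrays), an intensity trend with robust estimation, only the arrays of the 2 groups compared, the replicate number as a block, every probe as its own feature, and leaving out each array in turn. Leaving out IDE2 replicate 2 and IDE2+FGF2 replicate 2 together, and array quality weights, were added after the data were seen. A fit with the chip as a block was not run, since no chip is named.

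The fit and the list test were tried on simulated data with 200 of 9915 genes changed in 10 draws. Values were drawn as already normalized and filtered, with independent genes and equal spread in all groups. The rates therefore do not cover normalization or filtering and need not hold for the real arrays. For IDE2 against ES, 21.4% of changes of log2 1, 97.6% of log2 2 and 100% of log2 3 were recovered, 5.7% of calls were false, and the planted list was found in 10 draws, with 0.1 other lists called per draw. For IDE2+FGF2 against IDE2 the values were 20.6%, 97.8%, 100%, 6.2%, 10 and 0.3. The overlap of comparisons that share a control was set against 100 simulations without change. Replicate differences were compared with the error between beads at 95% confidence for probes with a signal above 500. T was not analysed here.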

Results

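Gene expression was measured on Illumina BeadChips in cells grown from the mouse embryonic stem (ES) cell line E14TG2a, in a study on how lung epithelium can be obtained from such cells. The 8 arrays formed 4 groups of 2. Undifferentiated ES cells (ES) were the control. A second group (IDE2) was kept for 11 days with 1 uM IDE2, a small molecule that induces definitive endoderm, the germ layer of gut and lung. The other groups received IDE2 for 6 days and then, for 5 days, either FGF2 at 500 ng/ml (IDE2+FGF2) or FGF10 at 25 ng/ml (IDE2+FGF10). FGF2 and FGF10 are fibroblast growth factors, and their doses differed. Between 11609 and 13422 of 25697 probes were detected per array, with median signals of 117 to 175 and median bead numbers of 38 to 40 per probe. The small number of arrays limits the precision of every value. The labels do not say whether the replicates of a group were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

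Undifferentiated cells lay far from all differentiated cells, and replicates of ES and of IDE2+FGF10 lay close together. Across genes, which are not independent replicates, Pearson's r between the replicates was 0.99 in ES, 0.958 in IDE2, 0.964 in IDE2+FGF2 and 0.99 in IDE2+FGF10. Between replicates, 176 genes differed at least 2-fold in ES, 1553 in IDE2, 1023 in IDE2+FGF2 and 180 in IDE2+FGF10. The difference exceeded the error between beads for 80.5% of bright genes in IDE2 and 72.7% in IDE2+FGF2, against 25.5% in ES, 12.2% in IDE2+FGF10 and an expected 5%. The first principal component held 60.2% of the variance and parted ES (-93.2 and -91.9) from the other arrays (2.20 to 42.5). On the second, with 19.2%, IDE2 replicate 2 lay at -68.4 and IDE2 replicate 1 at -12.6, while both IDE2+FGF10 arrays lay at 36.7. IDE2+FGF2 replicate 2 scored 2.20 on the first component and replicate 1 scored 26.6. All groups shared a single estimate of the spread of each gene, which by this measure is too small for IDE2 and IDE2+FGF2 (pooled SD within the group 0.496 and 0.454) and too large for ES and IDE2+FGF10 (0.247 and 0.241).

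**Figure D1:**
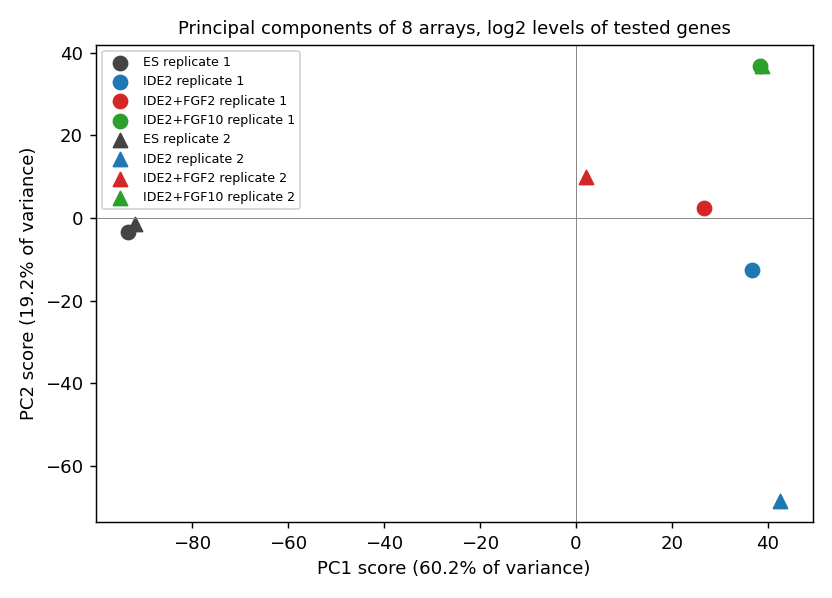
Scores of the 8 arrays on the first 2 principal components of the log2 levels of all tested genes; colours mark groups, circles replicate 1 and triangles replicate 2. ES arrays lie at -93.2 and -91.9 on the first component, and IDE2 replicate 2 lies at -68.4 on the second, where IDE2 replicate 1 lies at -12.6.

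The first comparison asked how cells after 11 days with IDE2 differed from undifferentiated ES cells. No group was kept for 11 days without IDE2. Effects of IDE2 therefore cannot be told apart from those of time and culture, here or in the other comparisons with ES. The transcript of smooth muscle actin, Acta2, rose 209-fold (log2 change 7.71 ± 0.27, SE, n = 2 arrays per group, adjusted p = 1.9e-07). The growth factor transcripts Ptn and Igf2 rose at least 203-fold and 107-fold, and Igfbp5, which encodes an insulin-like growth factor binding protein, rose at least 92.6-fold (adjusted p of 5.4e-07 or less). "At least" marks a gene whose probe was not detected on any array of the lower group, and its fold is taken against the background level there. Where the lower group was detected on 1 of its 2 arrays, the fold is given as measured but rests partly on background. Below this holds for Septin1, Plvap, Hspa1a, Zscan4c, Otx1 and Klhl6, among others. Among the largest falls were Etv4, an ETS factor induced by FGF signalling (68.9-fold), Utf1 (47.3-fold) and Klf2 (42.5-fold), transcription factors of ES cells, with adjusted p of 3.9e-06 or less. The pluripotency factor Pou5f1 (Oct4) fell 36.6-fold, from a log2 level of 15 ± 0.32 (SD, n = 2) to 9.81 ± 0.71, adjusted p = 6.5e-06, and Nanog fell 2.75-fold (adjusted p = 0.0016).

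Of the 23 tested genes of the pluripotency list, 20 fell, 1 rose (Dppa3, 2.58-fold) and 2 did not pass; the list shifted down (median log2 change -2.40, camera adjusted p = 2.4e-09; adjusted p = 0.13 with an estimated correlation). The call of Dppa3 ended without ES replicate 1 (adjusted p = 0.14) or IDE2 replicate 1 (1.57-fold, 0.099), and the fold was 4.15 without IDE2 replicate 2. Of 16 mesenchyme and fibroblast genes, 11 rose, among them Acta2 and the collagen gene Col5a1 (11.9-fold). Meox1 and the surface marker Thy1 (16-fold) fell and 3 did not pass. The median of that list was 1.70, or 1.40 with undetected genes at their bounds (camera adjusted p = 0.0067; adjusted p = 0.23 with an estimated correlation). Of 11 cholesterol synthesis genes, 5 rose, among them the sterol enzymes Nsdhl (10.6-fold) and Cyp51 (7.08-fold), and 6 did not pass. Their camera adjusted p was 0.049, or 0.23 with an estimated correlation, and 0.0057 to 0.09 over the alternatives. This last call was kept in 9 of 18 alternatives and lost in 9. It ended with no background correction (0.051), median scaling (0.052) and only the arrays of the 2 groups compared (0.09). Leaving out IDE2 replicate 1 or either IDE2+FGF2 array also ended it.

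The endoderm lists held many genes that rose, but neither passed as a list with all arrays. With IDE2 replicate 2 and IDE2+FGF2 replicate 2 both left out, extraembryonic endoderm passed. In definitive endoderm and early gut, 7 of 12 genes rose and 2 fell (camera adjusted p = 0.084). Risers were the simple epithelial keratins Krt18 (13.4-fold) and Krt8 (9.54-fold), the endoderm factor Sox17 (3.70-fold, adjusted p = 0.00099) and the receptor Cxcr4 (at least 2.39-fold), while Hhex fell 4.07-fold. In extraembryonic endoderm, 10 of 17 rose, such as Ttr (at least 6.52-fold), which encodes transthyretin, and Thbd (at least 5.24-fold), and 3 fell, such as Sox7 (3.06-fold; 0.084). The log2 change of Ttr, 3.20, was 2.26 and 4.11 without IDE2 replicates 1 and 2. In the lung epithelium list, 5 of 12 tested genes rose and 6 fell (median -0.52, 0.83). Pdpn, a marker of alveolar type I cells, rose 6.04-fold and Sox9 rose at least 2.25-fold. Napsa, which encodes an aspartic protease of alveolar type II cells, fell 13.3-fold. Etv5, which is also a member of the list of FGF targets, fell 5.93-fold. In other endoderm organs, 1 of 3 rose and 1 fell (0.97).

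Genes of other lineages also rose. In the neural list, 7 of 13 rose, such as Zic1 (at least 12.9-fold) and Gap43 (11.9-fold), and 2 fell, such as Crmp1 (5.05-fold; camera adjusted p = 0.084). In glia and neural crest, 3 of 8 rose, with Ednrb at least 21.6-fold higher, and 2 fell (0.39). In cardiac and skeletal muscle, 3 of 11 rose, with Actc1 at least 14.4-fold higher, and 2 fell (0.4). In trophoblast, 4 of 7 rose, with Krt7 at least 14.1-fold higher, and 1 fell (0.2). Endothelium and blood had 3 falls and 0 rises among 6 (Eng at least 8.67-fold lower, Pecam1 7.15-fold lower; 0.084), and macrophage and leukocyte 2 falls and 0 rises among 4 (Laptm5 13-fold lower; 0.12). In epiblast and primitive streak, 4 of 9 rose, with Fgf5 at least 16.4-fold higher, and 1 fell (0.24). Of 7 Nodal and activin targets, Gsc rose at least 2.52-fold and 3 fell, with Nodal itself 7.60-fold lower (0.46).

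Among the signalling and metabolic lists, 2 of 14 FGF feedback and target genes rose and 6 fell, with Spry4, an inhibitor of receptor tyrosine kinase signalling, at least 11.5-fold lower (camera adjusted p = 0.091). The p53 response had 7 rises and 1 fall among 10 (Cdkn1a, a cell cycle inhibitor, 3.90-fold higher; 0.084). Cell cycle had 2 rises and 1 fall among 15 (0.69), glycolysis and hypoxia 5 and 5 among 12 (0.96), and heat shock and stress 2 and 4 among 11 (Hmox1 9.01-fold lower; 0.67). Mitochondrial respiration had 0 rises and 2 falls among 11 (Cox5a 3.97-fold lower, or 6.07-fold and 2.62-fold without IDE2 replicates 1 and 2; 0.084), and cytosolic ribosome 0 rises and 1 fall among 10 (0.98). Adjusted over the list alone, the counts were the same for all lists but the last, where 0 passed. Mean, median and test differed in sign for other endoderm organs, glycolysis and hypoxia, and cytosolic ribosome.

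In all, 4496 of 9915 genes changed between IDE2 and ES by limma, 2294 higher and 2202 lower, and 1982 and 1906 of these changed at least 2-fold. The replicates of all of them did not overlap, as for 72.9% of all genes tested, where chance gives 33.3%. The count was 2697 without ES replicate 1 and 2761 without ES replicate 2. Of the 22 lists, 3 shifted by camera, or 11 without ES replicate 1. With an estimated correlation, where camera has only 4 degrees of freedom, 0 of 22 lists passed in any of the 6 comparisons. Here 3 had an unadjusted p under 0.05 by that test. Fry tests only whether a list moves on balance in a direction and does not compare it with other genes. It called 17.

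**Figure D2:**
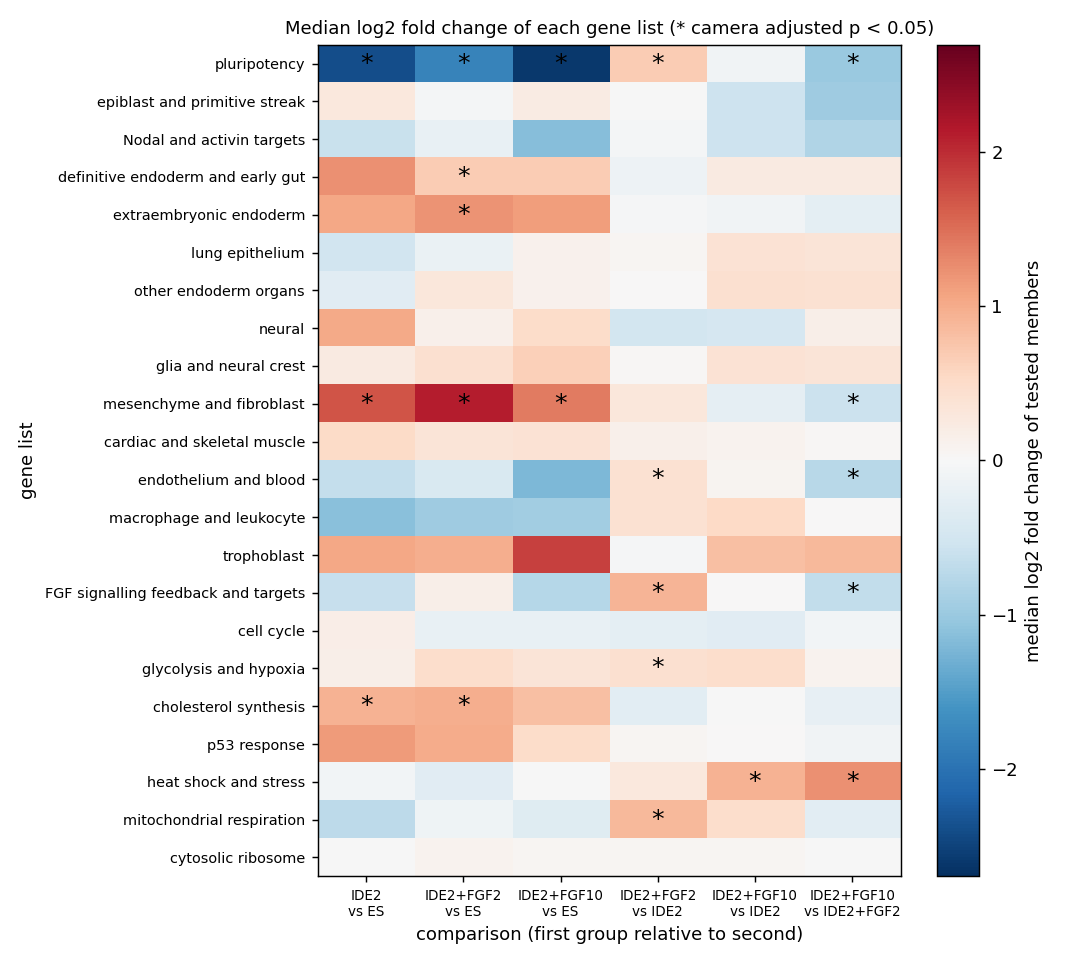
Median log2 fold change of the tested members of each of the 22 gene lists (vertical) in each of the 6 comparisons (horizontal), first group relative to second; an asterisk marks an adjusted p under 0.05 by camera with the preset correlation of 0.01. The pluripotency list has its lowest median, -2.61, in IDE2+FGF10 against ES, and the mesenchyme and fibroblast list its highest, 2.11, in IDE2+FGF2 against ES.

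With FGF2 after IDE2, Acta2 rose 191-fold over ES (log2 change 7.58 ± 0.27, SE, n = 2 per group, adjusted p = 2.2e-07). Bgn, which encodes the matrix proteoglycan biglycan, rose at least 76.7-fold, Igf2 104-fold, and Actc1, which encodes cardiac actin, at least 37.3-fold (adjusted p of 2.4e-06 or less). Among the largest falls were those of Septin1 (43.7-fold, or 24.3-fold and 76.7-fold without IDE2+FGF2 replicates 1 and 2), Exoc3l (27.6-fold) and Msc (at least 26.6-fold). Emcn, which encodes the endothelial sialomucin endomucin, rose at least 11.5-fold. Pou5f1 fell 7.18-fold, to 12.16 ± 0.58, and Nanog 2.54-fold (adjusted p of 0.00037 and 0.0034).

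In this group 18 of 23 pluripotency genes fell, among them Tbx3 (14.5-fold) and Klf2 (12.6-fold), 1 rose (Dppa3, 5.31-fold) and 4 did not pass. The list's median was -1.81 (camera adjusted p = 2e-08; adjusted p = 0.078 with an estimated correlation). In mesenchyme and fibroblast, 10 of 16 rose, such as Acta2 and Col3a1 (at least 9.33-fold), and Thy1 fell 3.15-fold (median 2.11, 2.4e-05; adjusted p = 0.078 with an estimated correlation). The Thy1 call ended without ES replicate 1, ES replicate 2 or IDE2+FGF2 replicate 1. In cholesterol synthesis, 6 of 11 rose and 0 fell, such as Cyp51 (5.80-fold) and Nsdhl (4.37-fold; median 0.98, 0.0063; adjusted p = 0.17 with an estimated correlation). In extraembryonic endoderm, 9 of 17 rose, such as Ttr (at least 7.95-fold) and Col4a2 (8.57-fold), and Sox7 fell 5.56-fold. The median of this list was 1.21, or 0.77 with undetected genes at their bounds (0.012; adjusted p = 0.17 with an estimated correlation). In definitive endoderm and early gut, 4 of 12 rose and 0 fell, with Krt18 14-fold and Krt8 7.17-fold higher (0.037, 0.025 to 0.087 over the alternatives; adjusted p = 0.22 with an estimated correlation). This call ended without IDE2+FGF2 replicate 1 (0.068) or ES replicate 2 (0.056). Sox17 was 1.77-fold higher and did not pass (adjusted p = 0.074). Adjusted over the list alone, the counts were the same for these lists, except for 10 rises in extraembryonic endoderm.

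The remaining lists did not pass against ES in IDE2+FGF2. Of 12 lung epithelium genes, 2 rose, Pdpn (4.54-fold) and Abca3 (3.54-fold), which encodes a lipid transporter of lamellar bodies, and 4 fell, such as Napsa (11.5-fold) and the mucin gene Muc1 (3.01-fold; camera adjusted p = 0.55). Of 14 FGF feedback and target genes, 6 rose, such as the MAP kinase phosphatase gene Dusp4 (5.65-fold), and 3 fell, such as Etv4 (4.93-fold, or 3.21-fold and 7.68-fold without IDE2+FGF2 replicates 1 and 2; 0.55). The counts adjusted over the list alone were the same for both. For epiblast and primitive streak the median was -0.06 and the mean 0.63, and the test pointed up; for endothelium and blood, camera pointed down and fry up.

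In all, 3423 genes changed between IDE2+FGF2 and ES by limma, 1760 higher and 1663 lower, and 70% of genes had non-overlapping replicates (33.3% by chance). The count was 1695 without ES replicate 1, 1774 without ES replicate 2, and 5317 without both IDE2 replicate 2 and IDE2+FGF2 replicate 2.

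With FGF10 after IDE2, Ptn rose at least 132-fold over ES and Acta2 156-fold (log2 change 7.29 ± 0.27, SE, n = 2 per group; adjusted p of 4.8e-07 or less). Igfbp4 rose 67.6-fold and Tmprss2, which encodes a serine protease, at least 36.0-fold. The stress transcription factors Ddit3 (CHOP) and Atf3 rose 24.0-fold and at least 17.8-fold (adjusted p of 3.5e-05 or less). The largest falls included Etv4 (60.6-fold), Tcf15 (49.5-fold) and the pluripotency list genes Klf2 (45.6-fold) and L1td1 (at least 43.6-fold). Pou5f1 fell 27.8-fold to 10.21 ± 0.12 and Nanog 6.60-fold (adjusted p of 1.1e-05 and 3.3e-05).

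Of the 23 pluripotency genes, 20 fell, 1 rose (Dppa3, 4.96-fold) and 2 did not pass (median -2.61, camera adjusted p = 1.4e-09; adjusted p = 0.12 with an estimated correlation). In mesenchyme and fibroblast, 10 of 16 rose, such as Acta2 and Col5a1 (9.09-fold), and 2 fell, Thy1 (11.5-fold) and Meox1 (at least 1.55-fold). The median was 1.40, or 1.33 with undetected genes at their bounds (0.016; adjusted p = 0.26 with an estimated correlation). The counts adjusted over the list alone were the same for both lists. Among definitive endoderm genes, Krt18 rose 24.4-fold and Krt19 13.4-fold, while Trh and Hhex fell 7.82-fold and 4.48-fold; the list did not pass (5 of 12 higher, 2 lower, 0.14; adjusted over the list alone, 6 and 3). Sox17 was 1.48-fold higher (adjusted p = 0.18). The heat shock and stress list had a median of -0.02 and a mean of 1.01, with 4 of 11 genes higher and 2 lower (0.27; the same adjusted over the list alone).

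Lung epithelium markers went both ways in IDE2+FGF10 relative to undifferentiated ES cells. Of 12 tested genes, 4 rose and 4 fell (camera adjusted p = 1, list alone 4 and 5), and median and mean differed in sign. Pdpn rose 6.11-fold and Abca3 4.54-fold, while Napsa fell 7.75-fold and Etv5 6.48-fold. Nkx2-1, the transcription factor that marks the lung field, was detected on 0 of 8 arrays, as were Sftpc, Sftpb and Scgb1a1, which encode proteins of alveolar type II and club cells, and Foxa2, Pax6 and Tubb3. These genes were not detectable at this signal over background, which does not show that they were absent. Brachyury (T) was not analysed here. The ciliated cell factor Foxj1 was 1.83-fold lower in IDE2 than in ES (adjusted p = 0.03) and did not pass in IDE2+FGF2 (0.36) or IDE2+FGF10 (0.93). The water channel gene Aqp5 fell at least 2.02-fold in IDE2 (0.012) and 2.38-fold in IDE2+FGF2 (0.042), and was 2.07-fold lower in IDE2+FGF10 without passing (0.066).

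In all, 4471 genes changed between IDE2+FGF10 and ES by limma, 2206 higher and 2265 lower, and 81.5% of genes had non-overlapping replicates (33.3% by chance). With median scaling, which moved the median of all genes by -0.22, the split was 1589 to 2889. The count was 2762 and 2828 without ES replicates 1 and 2, and 2951 and 2934 without IDE2+FGF10 replicates 1 and 2. Across the comparisons of all 3 differentiated groups with ES, 1162 genes rose in each and 1169 fell in each, where independence gives 90.6 and 84.4. In 100 simulations with shared controls and no change, the mean overlap was 0, but almost no gene passes there, so this does not measure what the shared ES arrays add. Controls shared by all comparisons could not be split, so part of the excess may come from them. Across genes, the changes correlated at 0.845 (IDE2 and IDE2+FGF2), 0.836 (IDE2 and IDE2+FGF10) and 0.859 (IDE2+FGF2 and IDE2+FGF10), where the simulations gave 0.499, 0.501 and 0.499. The covariances were 1.37, 1.6 and 1.39, against simulated ones of 0.0596, 0.0598 and 0.0596. The simulated spread was larger than that of ES (SD 0.247), so the shared ES arrays add little to these covariances. Their part in the count of overlapping genes was not measured.

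FGF2 after IDE2 was compared with IDE2 alone to ask what replacing IDE2 by FGF2 for the last 5 days changed. The loss of IDE2 and the addition of FGF2 coincide, so their effects cannot be told apart. Emcn rose at least 13.3-fold (log2 change 4.54 ± 0.27, SE, n = 2 per group, adjusted p = 2.2e-05), Plvap, a gene of fenestrated endothelium, 12.5-fold, and the TGF-beta co-receptor gene Eng at least 5.23-fold. The FGF target genes Etv4 and Dusp4 rose 14-fold and 13.4-fold (adjusted p of 0.00042 and 7e-05). The fold of Etv4 was 21.4 and 9.2 without IDE2+FGF2 replicates 1 and 2. Among the falls were the transcription factors Tfap2b (at least 25.8-fold) and Egr2 (21.3-fold), the ligand gene Wnt3a (at least 15.4-fold) and the endothelin receptor gene Ednrb (9.12-fold) (adjusted p of 0.00033 or less). The cerebellin gene Cbln1 fell 28-fold, and the FGF ligand gene Fgf8 6.60-fold.

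Of the 14 FGF feedback and target genes, 4 rose, 0 fell and 10 did not pass; adjusted over the list alone, 8 rose. The median was 0.93 (camera adjusted p = 6.3e-05, or 0.17 with an estimated correlation). That estimate, -0.036, lay below the preset correlation, so it is not what raised the p. Of 23 pluripotency genes, 5 rose, such as Utf1 (13.5-fold) and Pou5f1 (5.09-fold), and Sox2 fell 2.02-fold. Adjusted over the list alone, 7 rose and 1 fell; the median was 0.69, or 0.58 with undetected genes at their bounds (0.0024, 4.6e-05 to 0.14 over the alternatives; adjusted p = 0.33 with an estimated correlation). Pou5f1 was 3.69-fold higher without IDE2 replicate 2 (adjusted p = 0.075) and 3.89-fold without IDE2+FGF2 replicate 2 (0.1) and did not pass there, and the list did not pass without IDE2+FGF2 replicate 1 (0.14). In endothelium and blood, Emcn and Eng rose and 4 did not pass (the same over the list alone; median 0.42, or 0.27 at the bounds; 0.023, 0.0084 to 0.55 over the alternatives; adjusted p = 0.33 with an estimated correlation). Of the 15 genes of that list, 9 were not above background on 2 arrays, the endothelial genes Kdr, Cdh5 and Tie1 among them. The list did not pass without IDE2 replicate 1 or with either IDE2+FGF2 array left out. Emcn was not tested with an IDE2+FGF2 array left out, so the list then lacked its largest rise.

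In glycolysis and hypoxia, the adrenomedullin gene Adm rose 9.53-fold, Aldoa 3.01-fold and 10 genes did not pass; adjusted over the list alone, 5 of 12 rose (median 0.43, camera adjusted p = 0.023; adjusted p = 0.33 with an estimated correlation). Without IDE2 replicate 1 its p was 0.4 and without IDE2+FGF2 replicate 1 0.083, in a range from 0.00088 over the alternatives. In mitochondrial respiration, 0 of 11 genes passed in limma, and 2 rose adjusted over the list alone; the median was 0.87 (0.023; adjusted p = 0.58 with an estimated correlation). Its p was 0.19 without IDE2 replicate 2, in which mitochondrial ribosome genes were also lower than in IDE2 replicate 1 (median difference -1.2, 63 of 71 lower), and 0.24 without IDE2+FGF2 replicate 1, in a range from 0.0059. In the lung epithelium list Etv5 rose 3.18-fold and 3 of 12 fell, such as Id2 (2.46-fold) and Trp63 (at least 2.12-fold), the same adjusted over the list alone (0.64). Without IDE2+FGF2 replicate 2, Etv5 was 2.08-fold higher and none of these 3 genes passed (adjusted p of 0.26, 0.17 and 0.2), and without replicate 1 Etv5 was 4.87-fold higher. These 3 calls, and that of Sox2, also ended without either ES array or either IDE2+FGF10 array (adjusted p of 0.061 to 0.11). Median and test differed in sign for lung epithelium and for glia and neural crest, where the median was 0.02, the mean -0.44 and fry pointed down (0.014); they also differed for extraembryonic endoderm and trophoblast.

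**Figure D3:**
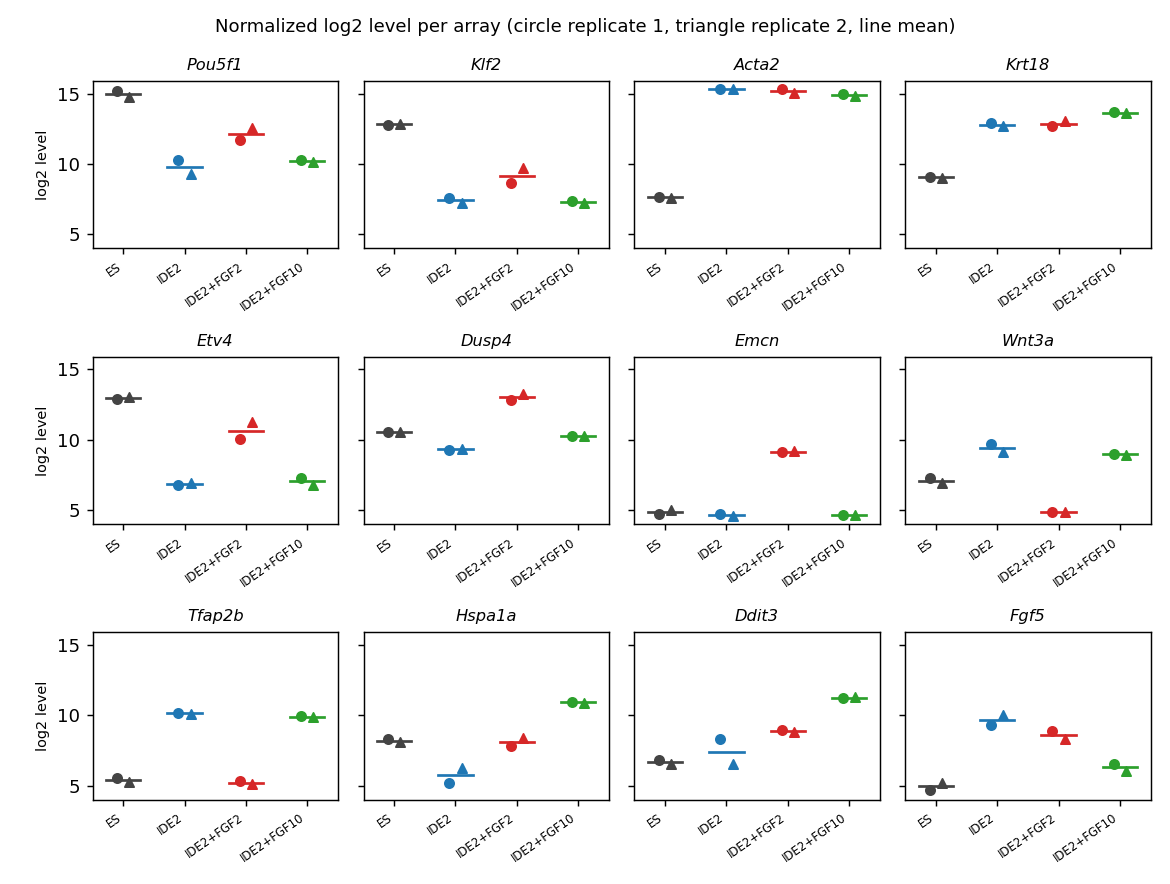
Normalized log2 level of 12 genes on each of the 8 arrays, by group; circles are replicate 1, triangles replicate 2 and lines group means. Pou5f1 lies at 15 in ES and 9.81 in IDE2, Dusp4 and Emcn are highest in IDE2+FGF2 (13.05 and 9.16), and Hspa1a is highest in IDE2+FGF10 (10.92).

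In all, 744 genes changed between IDE2+FGF2 and IDE2 by limma, 367 higher and 377 lower (515 and 311 with median scaling), and 48.2% of genes had non-overlapping replicates (33.3% by chance). The count was 336 and 348 without ES replicates 1 and 2, 2369 and 174 without IDE2 replicates 1 and 2, 1326 and 89 without IDE2+FGF2 replicates 1 and 2, and 376 and 364 without IDE2+FGF10 replicates 1 and 2. With only the arrays of these 2 groups it was 254, of which 253 were among the 744. Of the 43 named genes that passed, 17 were tested and passed under each of 19 alternatives, Plvap, Etv4, Utf1, Dusp4, Tfap2b, Cbln1, Wnt3a, Egr2, Ednrb, Fgf8, Adm and Zic1 among them. Emcn passed wherever it was tested, but was not tested under the strict filter or with an IDE2+FGF2 array left out, since it was detected on the 2 arrays of that group alone. Of those tested, 19 of 40 did not pass without IDE2+FGF2 replicate 2, and 14 of 41 without IDE2 replicate 2.

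FGF10 after IDE2 was compared with IDE2 alone in the same way. Here too, the loss of IDE2 and the addition of FGF10 cannot be told apart. Stress genes stood at the top of the rises. Hspa1a, which encodes an inducible Hsp70, rose 36.4-fold (log2 change 5.18 ± 0.37, SE, n = 2 per group, adjusted p = 0.00032). Its probe was detected on 1 of 2 IDE2 arrays. Ddit3 rose 14.2-fold, Gadd45b 5.27-fold and Ppp1r15a, a gene of the integrated stress response, 5.16-fold (adjusted p of 0.0076 or less). The fold of Ddit3 was 26.2 and 7.9 without IDE2 replicates 1 and 2. The MHC class II gene H2-Ab1 rose 9.08-fold. The epiblast gene Fgf5 fell 10.4-fold, L1td1 at least 5.93-fold, and Zscan4c, a gene of rare ES cells in a 2-cell-like state, 8.2-fold. The endoderm genes Sox17 and Cxcr4 fell 2.50-fold and at least 2.20-fold (adjusted p of 0.026 and 0.033), and Nanog fell 2.40-fold (0.016). Without IDE2 replicate 2 these 3 did not pass (0.12, 0.18 and 0.065), and the log2 change of Cxcr4 was -0.80 instead of -1.39. The call of Cxcr4 also ended without either ES array (0.058) or either IDE2+FGF2 array (0.056).

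Of 11 heat shock and stress genes, 5 rose, 0 fell and 6 did not pass, or 6 rose adjusted over the list alone (median 0.93, camera adjusted p = 0.0057, 0.00027 to 0.14 over the alternatives; adjusted p = 0.36 with an estimated correlation). The list did not pass without IDE2 replicate 1 (0.14). Of 14 FGF feedback and target genes, 4 rose, such as the early response gene Ier3 (8.67-fold, or 15.1-fold and 5.09-fold without IDE2 replicates 1 and 2), and Spred1 fell 2.78-fold (camera adjusted p = 0.61). Of 23 pluripotency genes, Utf1 rose 2.54-fold, 4 fell and 18, Pou5f1 among them, did not pass (0.81). The counts adjusted over the list alone were the same for both. In glycolysis and hypoxia, 4 of 12 rose, such as Adm (4.75-fold) and Aldoa (2.74-fold), and the list missed the threshold (0.053; adjusted over the list alone, 5 rose). In the lung epithelium list, Trp63 fell at least 1.71-fold and 11 of 12 genes did not pass (0.61; adjusted over the list alone, 2 rose and 2 fell). In definitive endoderm and early gut, 1 of 12 rose (Krt19, 2.85-fold) and 4 fell, with a median of 0.23 and a mean of -0.11 (0.92; adjusted over the list alone, 3 rose and 4 fell). Mean and median also differed in sign for endothelium and blood.

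In all, 1377 genes changed between IDE2+FGF10 and IDE2 by limma, 409 higher and 968 lower, and 65.5% of genes had non-overlapping replicates (33.3% by chance). Median scaling moved the median of all genes by -0.18 and gave 194 and 1410, while without IDE2 replicate 1 the split was nearly even (1526 and 1696). The count moved strongly with the arrays used, and why was not tested. It rose without IDE2 replicate 1 and fell without IDE2 replicate 2, either IDE2+FGF10 array or either ES array. It was 0 in limma with only the 4 arrays compared, where 2828 genes had an unadjusted p under 0.05. That fit changes both the spread and the degrees of freedom. With array quality weights the count was 898, of which 893 were among the 1377. None of the 50 named genes that passed did so under every alternative in which it was tested; 46 and 49 of 50 did not pass without IDE2+FGF10 replicates 1 and 2, and 31 of 47 without IDE2 replicate 2. Hspa1a failed only in the fit to those 4 arrays (adjusted p = 0.087). Against IDE2, 80 genes rose and 180 fell in both growth factor groups (15.1 and 36.8 by independence), and 6 went opposite ways. The changes correlated at 0.577 across genes, with a covariance of 0.339. Shared IDE2 arrays gave 0.5 and 0.0596 in simulations with equal spread in all groups. IDE2 varied more than IDE2+FGF10 (SD 0.496 and 0.241), so these arrays alone can give values above the simulated ones. The correlation therefore does not show a shared response, and part of the overlap may come from the shared arrays. The covariance that the shared arrays would add at that SD of IDE2, however, stays below the observed 0.339.

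The groups given the 2 growth factors were compared directly, at different doses. Higher with FGF10 were Tfap2b (at least 21.8-fold, log2 change 4.68 ± 0.27, SE, n = 2 per group, adjusted p = 2.3e-05), the ligand genes Wnt3a (at least 11.4-fold) and Wnt1 (at least 5.99-fold), and Otx1 (10.2-fold). Cbln1 was 21.2-fold higher, and Crabp2 and Crabp1, which encode retinoic acid binding proteins, were 14.1-fold and 9.33-fold higher. The fold of Crabp1 was 18.4 without IDE2+FGF2 replicate 1 and 4.82 without replicate 2, where it did not pass (adjusted p = 0.086). Lower with FGF10 were Emcn (at least 10.6-fold), Klhl6 (13.4-fold), Etv4 (12.3-fold) and Dusp4 (6.88-fold), with adjusted p of 0.00091 or less. The fold of Etv4 was 18.8 and 8.1 without IDE2+FGF2 replicates 1 and 2. Pou5f1 was 3.87-fold and Nanog 2.59-fold lower with FGF10 (adjusted p of 0.018 and 0.016).

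Of 11 heat shock and stress genes, 7 were higher with FGF10, such as Hspa1a (7.16-fold) and Ddit3 (5.13-fold), and 0 were lower; adjusted over the list alone, 8 were higher (median 1.23, camera adjusted p = 0.00019; adjusted p = 0.12 with an estimated correlation). Of 23 pluripotency genes, 8 were lower, such as L1td1 (at least 5.08-fold; log2 change -2.90, or -2.31 without IDE2+FGF2 replicate 1) and Utf1 (5.30-fold), and 0 higher, or 13 lower and 1 higher adjusted over the list alone (median -1, or -0.74 at the bounds; 0.00019; adjusted p = 0.12 with an estimated correlation). Of 14 FGF feedback and target genes, 5 were lower, such as Etv4 and Dusp4, and 0 higher, or 6 lower and 1 higher over the list alone (median -0.66, or -0.63 at the bounds; 0.0026; adjusted p = 0.12 with an estimated correlation). Of 16 mesenchyme genes, 4 were lower, such as Thy1 (3.65-fold) and Col3a1 (3.42-fold), or 5 over the list alone (median -0.57, or -0.41 at the bounds; 0.0031, 0.00028 to 0.057 over the alternatives; adjusted p = 0.12 with an estimated correlation). In endothelium and blood, Emcn and Eng were lower and 4 did not pass, with 3 lower over the list alone. Its median was -0.75, or -0.06 at the bounds (camera adjusted p = 0.0046, or 0.12 with an estimated correlation). The call was kept in 14 of 18 alternatives. It ended with either IDE2+FGF2 array left out, where Emcn was not tested.

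Of the lung epithelium genes, Id2 was 2.32-fold higher and Etv5 3.47-fold lower with FGF10, and 10 of 12 did not pass (camera adjusted p = 0.15, the same counts adjusted over the list alone). Etv5 was 5.33-fold and 2.29-fold lower without IDE2+FGF2 replicates 1 and 2, and neither gene passed without replicate 2 (adjusted p of 0.17 for Id2 and 0.18 for Etv5) or without either ES array (0.058 to 0.1). Median, mean or test differed in sign for definitive endoderm, other endoderm organs, neural, cardiac and skeletal muscle, macrophage and leukocyte, glycolysis and hypoxia, and cytosolic ribosome, none of which passed.

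In all, 725 genes changed between IDE2+FGF10 and IDE2+FGF2 by limma, 258 higher and 467 lower, and 59.7% of genes had non-overlapping replicates (33.3% by chance). Median scaling moved the median of all genes by -0.27 and gave 136 higher and 1237 lower, while without IDE2+FGF2 replicate 1 the split was nearly even (511 and 522). The count was 365 and 369 without ES replicates 1 and 2, 1491 and 1582 without IDE2 replicates 1 and 2, 132 without IDE2+FGF2 replicate 2, and 93 and 69 without IDE2+FGF10 replicates 1 and 2. Of the 48 named genes that passed, 17 were tested and passed under each of the 19 alternatives, Tfap2b, Cbln1, Wnt3a, Wnt1, Otx1, Crabp2, Etv4, Dusp4, L1td1 and Hspa1a among them. Emcn, not tested under the strict filter or with an IDE2+FGF2 array left out, and Klhl6, not tested under that filter, passed in the others. Of those tested, 24 and 26 of 48 did not pass without IDE2+FGF10 replicates 1 and 2, and 21 of 44 without IDE2+FGF2 replicate 2. Pou5f1 (0.11, 0.14 and 0.13), Crabp1, Utf1, Ddit3 and Thy1 did not pass in any of these 3 fits.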

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

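The alternatives without both doubted libraries (IDE2 replicate 2 and IDE2+FGF2 replicate 2) and with array quality weights were chosen after the results were seen. The cause of the moves below was not tested. Fewer arrays leave fewer degrees of freedom, which would not by itself raise a count. Leaving out an array also changes the shared spread, which takes in pairs as unlike as ES (SD 0.247) and IDE2 (0.496). A call that ended without an array outside its comparison therefore need not rest on what that array measured. Where an array was left out, the lone array of its group is assumed to vary like the other groups. The order of values is IDE2, IDE2+FGF2 and IDE2+FGF10 against ES, IDE2+FGF2 and IDE2+FGF10 against IDE2, and IDE2+FGF10 against IDE2+FGF2. Leaving out each array in turn gave 2697 to 4826, 1695 to 4217, 2762 to 5176, 89 to 2369, 1 to 3222 and 69 to 1582 changed genes, and 2 to 11, 5 to 6, 2 to 4, 1 to 5, 0 to 3 and 4 to 5 shifted lists. The lowest gene counts against IDE2 came without IDE2+FGF2 replicate 2 (89) and IDE2+FGF10 replicate 2 (1), and the highest without IDE2 replicate 1 (2369 and 3222). With a replicate block, 4407, 3360, 4367, 638, 1324 and 665 genes and 3, 5, 2, 5, 1 and 5 lists passed; the labels do not pair the replicates. No fit with the chip as a block was run.

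Gene counts moved beyond 1.5 times elsewhere as follows. IDE2+FGF2 against ES had 5317 without both doubted libraries. IDE2+FGF2 against IDE2 (744) had 489 with no detection filter, 335 without both doubted libraries, 73 with array quality weights and 254 with only the 2 groups compared. IDE2+FGF10 against IDE2 (1377) had 898 with array quality weights and, by limma with only the 2 groups compared, 0 (2828 at an unadjusted p under 0.05). IDE2+FGF10 against IDE2+FGF2 (725) had 1373 with median scaling, 2364 without both doubted libraries and 382 with only the 2 groups compared. Of the genes called with all arrays, the fit of 2 groups shared 253 of 744, 0 of 1377 and 356 of 725. Array weights were equal within each group (2.25 in ES, 0.354 in IDE2, 0.467 in IDE2+FGF2, 2.68 in IDE2+FGF10), since 2 arrays cannot be ranked against each other.

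List counts moved as follows. IDE2 against ES (3) had 6 with no detection filter and 6 with the strict detection filter. IDE2+FGF10 against ES (2) had 4 with median scaling, no detection filter, without both doubted libraries and only the 2 groups compared, and 7 with the strict detection filter. IDE2+FGF2 against IDE2 (5) had 3 without both doubted libraries. IDE2+FGF10 against IDE2 (1) had 3 with no background correction, median scaling, series matrix values and without both doubted libraries, and 4 with no detection filter. With an estimated correlation, camera called 0 lists in each comparison (3, 4, 2, 3, 1 and 5 at an unadjusted p under 0.05), and fry called 17, 16, 17, 8, 5 and 6. Lists called in all 18 settings other than these were pluripotency and mesenchyme in the 3 comparisons with ES, cholesterol synthesis and extraembryonic endoderm in IDE2+FGF2 against ES, FGF targets in IDE2+FGF2 against IDE2, and FGF targets, stress and pluripotency in IDE2+FGF10 against IDE2+FGF2.

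Of 7281 values of named genes under alternatives, 6561 kept their direction and side of the threshold, 714 lost a call, 1 gained it and 5 changed sign, all of them for genes that had not passed. Nanog in IDE2+FGF2 against IDE2 was -0.0329 without IDE2 replicate 1 and -0.0367 without IDE2+FGF2 replicate 1, in a range to 0.263 over single arrays left out. Pou5f1 in IDE2+FGF10 against IDE2 was -0.105 without IDE2 replicate 2 (range to 0.898) and -0.107 without both doubted libraries. Sox17 in IDE2+FGF10 against IDE2+FGF2 was 0.127 without IDE2+FGF10 replicate 1 (range from -0.657). Signal over background limits what can be seen: 45.2 to 52.2% of probes were detected, and Nkx2-1, Sftpc, Sftpb and Scgb1a1 were not.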

Other observations

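Gene families were chosen after their values were seen, and 3 of the tests of explanations as well: those on array quality, on a culture further along, and on the pluripotency genes at the share the other genes need. The directions of the families in this paragraph were the same with no background correction, median scaling and series matrix values, and without IDE2 replicate 2. Without background correction their medians were smaller. For collagens against ES they were 0.59 in IDE2, 0.44 in IDE2+FGF2 and 0.53 in IDE2+FGF10. Collagen genes rose against ES: of 22 tested (6 of which are also in a list), 12 were higher and 1 lower in IDE2 (median 1.34, camera adjusted p = 0.004; 0.2 with an estimated correlation), 12 and 0 in IDE2+FGF2 (1.10, 0.00011; 0.1), and 12 and 2 in IDE2+FGF10 (1.23, 0.0045; 0.18). Of 8 genes for insulin-like growth factors and their binding proteins, 6, 5 and 7 were higher and 0 lower (medians 2.48, 2.95 and 2.58; 0.0011, 0.00011 and 0.00056; with an estimated correlation 0.2, 0.1 and 0.18). Of 10 Wnt genes, 6 rose in IDE2 (1.34, 0.0099; 0.36) and 7 in IDE2+FGF10 (1.45, 0.015; 0.42) against ES; 3 fell and 1 rose in IDE2+FGF2 against IDE2 (-1.11, 0.0021; 0.62), and 4 were higher in IDE2+FGF10 than in IDE2+FGF2 (1.05, 0.0043; 0.59).

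In IDE2+FGF10 against IDE2, 10 of 43 histone genes rose and 0 fell (median 1.33, camera adjusted p = 2.1e-08; 0.71 with an estimated correlation), 52 of 182 zinc finger genes named Zfp fell and 2 rose (-0.53, 2.1e-08; 0.63), and 5 of 17 MHC genes rose and 0 fell (0.63, 0.0023; 0.63). Without IDE2 replicate 2 no histone gene passed in limma (median 0.51; by camera of limma the family still shifted, unadjusted p = 0.00052), 9 of 172 Zfp genes fell (-0.41) and 1 of 16 MHC genes rose (0.31). These 3 directions were the same under each of those settings. In IDE2 against ES, 25 of 71 mitochondrial ribosome genes fell and 1 rose (median -0.79, camera adjusted p = 0.00024; 0.77 with an estimated correlation), but 63 of 71 were lower in IDE2 replicate 2 than in replicate 1, as short genes were, and without IDE2 replicate 2 the median was -0.24, with 20 lower and 2 higher. The histone median there was -0.58 and turned to 0.25 without IDE2 replicate 2.

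IDE2 replicate 2 stood apart from IDE2 replicate 1. Its 13422 detected probes, the most of the 8 arrays, argue against an array with weak detection. They cannot speak to the quality of the RNA or its labelling. A culture further along the same path is argued against by a Spearman rho of -0.12 across genes with the change from ES to IDE2+FGF10. The bound of that last test, 0.1 or less, was changed after the value was seen. Across 9874 genes, which are not independent replicates, the difference rose with gene span (rho 0.41, against -0.017 in ES, 0.013 in IDE2+FGF2 and 0.0045 in IDE2+FGF10; median -0.45 in the 20% of genes with the shortest span and 0.28 in the 20% with the longest), so short transcripts may be under-represented in this library, although genomic span is a weak stand-in for transcript length and also follows biology. A separate test on mitochondrial ribosome genes (63 of 71 lower, median -1.2; medians 0.053, -0.2 and -0.027 in the other groups) was dropped because these genes are short and it would repeat the test on span. Another biological difference between the samples was not tested.

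IDE2+FGF2 replicate 2 lay nearer to ES than replicate 1. Short or long transcripts favoured in this library are argued against by a rho of 0.013 with gene span. Of 374 genes high in ES, 72.2% were higher in replicate 2, between the bounds of 60 and 75 set before the value, though after the position in the principal components, and 25.9% of 491 genes low in ES were higher; whether more undifferentiated cells remained cannot be told apart on this test. At the 6.1% share of ES signal that those 374 genes would need, 50% of 12 pluripotency genes (Esrrb, Gdf3, Klf5, L1td1, Tbx3 and Zfp42) fell short by over 0.5 log2 units, which leaves this open as well; the gene set, tolerance and bounds of this test were changed after a first look. Of the pluripotency list, 8 of 23 genes were higher in replicate 2 (median -0.13), and a slower or different course of differentiation in that sample was not tested.

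Stress genes were higher in IDE2+FGF10 than in the other differentiated groups. IDE2 replicate 2 alone is argued against, because the stress list passed without it (camera adjusted p = 0.00027, within 0.00027 to 0.14 over the alternatives, the highest without IDE2 replicate 1; adjusted p = 0.36 with an estimated correlation and all arrays). Against IDE2+FGF2, 7 of 11 stress genes were also higher (camera adjusted p = 0.00019; 0.12 with an estimated correlation). A general handling response at harvest cannot be told apart: 11 immediate-early genes had a median of 0.31 against IDE2+FGF2 (3 higher, 1 lower, 8 positive) and 1.4 against IDE2 (7 higher, 1 lower), and members moved both ways. Of these genes, Egr1, Fos and Ier3 are also in the list of FGF targets, so the IDE2+FGF2 group is a poor reference for them. Atf3 is itself in the stress list. An effect of FGF10 itself may explain the change too, but each treatment coincides with its own samples, so the design cannot part them.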
